A study of Mus musculus with 30 samples.

How the data were processed

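Gene expression was measured in mouse embryonic stem (ES) cells on 30 Illumina BeadChip arrays, a 1-colour platform that carries 24611 probes in the tables used here. Per the labels, the cells were of the Ainv15 line, in which a doxycycline-controlled promoter drives a gene placed at a fixed site. The arrays covered 28 biological samples in 7 groups of 4. Each culture was treated for 6 hours. The groups were ES cell medium (ESC), serum-free N2B27 medium (N2B27), N2B27 with doxycycline at 2 ug/ml (Dox), N2B27 with the gamma-secretase inhibitor DAPT at 2.5 ng/ml as the labels give it, following 4 hours of DAPT in ES cell medium (DAPT), N2B27 under 1% oxygen (1% O2), and the last condition with doxycycline (1% O2+Dox) or, following the same pretreatment, with DAPT (1% O2+DAPT). DAPT was thus present in the pretreatment and in the 6 hours. The sample titles do not give the medium of the controls before their 6 hours. The DAPT groups may therefore also differ from their controls by the pretreatment period in ES cell medium. Dox samples 3 and 4 were each hybridised on a second array, and these 2 technical arrays were averaged with the first array of the same sample.

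The main table holds an intensity per probe and array on a linear scale, not normalized between arrays per the file headers. Per the submitters' processing notes the program was BeadStudio, with no version given. Between 27.2% and 29.9% of the deposited intensities on each array were below 0, so a background had already been subtracted. The table gives no detection p-values and no control probes. A second deposited table holds the authors' processed intensities of the same arrays. All 30 of its columns correlated best with their own array in the main table, and on the first array 99.96% of its values equalled the main table's signal or a floor of 50. The scale is therefore linear, genes were not centred, and the direction is that of the signal, while the method that brought the arrays together is not given in the sources used here. Its median was 50 on every array because 53.8% to 56.0% of values lay at the floor. It served as an alternative only.

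Negative signals have no logarithm. The background was therefore corrected with the normexp model of limma 3.58.1 (R 4.3.3) at an offset of 0, followed by log2 and quantile normalization across the arrays. Probes were named through GEO's platform annotation, updated through the Entrez number for 20967 of them. Of all probes, 20983 had 1 gene symbol, 1 had several and 3627 had none. A named probe was kept where it exceeded its own array's median on at least 4 of the 28 samples, which left 12259 probes. Each gene was represented by its probe with the highest mean, giving 9809 genes tested, of which 1946 had a second probe that passed.

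Arrays give no read depth, and their number limits the precision. The mean signal per array ranged from 645 to 862. As no detection p-values exist, a background limit was set for each array after seeing the data, at the 98th percentile of its negative signals mirrored around 0 (29.3 to 41.6 signal units). Between 47.7% and 49.9% of probes lay above it. Where every array of a group lay at or below its limit, the change is given as "at least N-fold", with the bright group's mean set against the dim group's mean of, per array, the higher of the limit and the probe's own value.

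All 28 samples entered 1 linear model per gene with a mean for each group (lmFit and eBayes in limma, 21 residual degrees of freedom). There were 6 main comparisons between pairs of groups, 2 further contrasts compared oxygen levels within Dox and within DAPT, and 2 interactions tested whether the Dox or the DAPT effect differed between oxygen levels. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called changed. Every adjusted p-value printed for a gene comes from this limma model unless another fit is named, and log2 fold changes carry the model's standard error (SE). The tests are two-sided. The labels call the samples biological replicates but do not say that they came from separate cultures or days, so p-values measure only the spread between these samples, which may in part be technical. Over the genes tested, log2 values of the repeat arrays of Dox samples 3 and 4 differed by an SD of 0.212 and 0.232. First arrays of Dox samples 3 and 4 differed by 0.248, of 1 and 2 by 0.268, and of 1 and 3 by 0.541. Samples 3 and 4 thus differed little more than repeat arrays of 1 sample.

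Before the data were examined, 30 gene lists (707 members, 510 of them measured) were fixed: canonical Notch targets, Notch pathway components, HIF targets, glycolysis, respiratory chain subunits, JmjC histone demethylases, cholesterol and fatty acid synthesis, pluripotency, LIF and STAT3 targets, serum immediate early genes, SRF and actin genes, targets of the BMP, Nodal, Wnt, FGF and retinoic acid pathways, markers of neural, mesoderm, endoderm, trophectoderm and fibroblast cells, the integrated stress response, endoplasmic reticulum chaperones, heat shock genes, NRF2 and metal response, p53 targets, S phase, G2 and mitosis, and ribosomal proteins. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists of a comparison, and again with an estimated correlation and with fry. Counts of changed members are also given adjusted over the list alone.

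The genes named were fixed by a rule set before the data were examined. In each main comparison these are the 8 largest rises and 8 largest falls among genes past the threshold with every sample of one group above every sample of the other, and up to 3 changed members of the Notch and HIF lists, of each list called by camera and of each list with 5 or more changed members. In the other contrasts they are the 6 largest changes. A set of 10 genes is named in any case: Notch1, Hes1, Hes5, Hey1, Nrarp, Vegfa, Car9, Egln3, Pou5f1 and Nanog. Genes known only by a clone or predicted identifier were passed over (1 gene). Exceptions are marked as chosen after their values were seen.

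Replicate numbers recur in every group, so the same model was also fitted with the number as a block (18 residual degrees of freedom). Whether the numbers pair the samples was checked before the fits were compared: deviations from the group means correlated at 0.704 or more in each of 84 pairs of samples with the same number (median 0.786), and 28 of 28 samples correlated best with samples of their own number. The numbers come from the labels, and they pair the samples on this evidence. The main model was fixed in advance without the block, and blocked values stand beside the results they move. The samples also fall into 2 replicate sets, replicates 1 and 2 against replicates 3 and 4, and the labels do not say what parts them. Across these sets the correlations of deviations ran from -0.772 to -0.598, and results within each set are given too. No slide numbers were found for the arrays.

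The model was tested on simulated data over 9809 genes. With changes of log2 0.5, 1, 1.5 and 2 put into 50 genes each, it recovered 46%, 82%, 94% and 98% of them for Dox against N2B27 with no false call, and 84%, 100%, 100% and 100% with the block, with 4 false calls among 196. For 1% O2+Dox against 1% O2 it recovered 38%, 84%, 90% and 98% without the block. Of 99 simulated unchanged lists, 0 were called. These lists were drawn at random and the residuals of each gene were simulated independently, so lists whose members vary together were not tested.

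Alternatives fixed in advance were no background correction (a floor of 16), median scaling or cyclic loess in place of quantile normalization, the authors' processed intensities, no filter or a stricter one (14 samples), every probe in place of 1 per gene, a model with only the compared groups, array weights, a variance trend, the technical arrays left out, a threshold of 0.01 or a fold of at least 1.5, the replicate block and each sample left out in turn. Chosen after seeing the data were a normexp offset of 50, a 2-level term for the replicate sets, each set alone, and effects averaged over both oxygen levels. Samples were left out in the main model without the block, so each omission also unbalances the replicate sets. The figures were drawn with matplotlib 3.10.9.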

Results

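The arrays profiled 28 samples of mouse ES cells, 4 in each of 7 groups, to ask how Notch signaling and low oxygen act on the same cells over 6 hours. As known of the study, doxycycline switches on the intracellular domain of Notch1 in these cells, the form that activates transcription, and DAPT blocks the gamma-secretase cleavage that releases it from the receptor. The labels name both compounds but not the transgene. No group without the transgene received doxycycline, so effects of the drug itself cannot be told from those of the transgene. N2B27 is the control medium for all groups except ESC. The first principal component, 51.5% of the variance, separated replicates 1 and 2 from replicates 3 and 4 in every group, and the second, 18.3%, separated the samples kept under 1% oxygen from all others. Of 9809 genes tested, 6885 differed between these sets of replicates, whose origin the labels do not give, 557 of them at least 2-fold. That fit took the 28 samples as independent. Samples of the same replicate number vary together, so it sets 2 numbers against 2 and the count may be too high. The difference between the sets enters the spread of the model without the replicate block and is removed by the block.

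**Figure D1:**
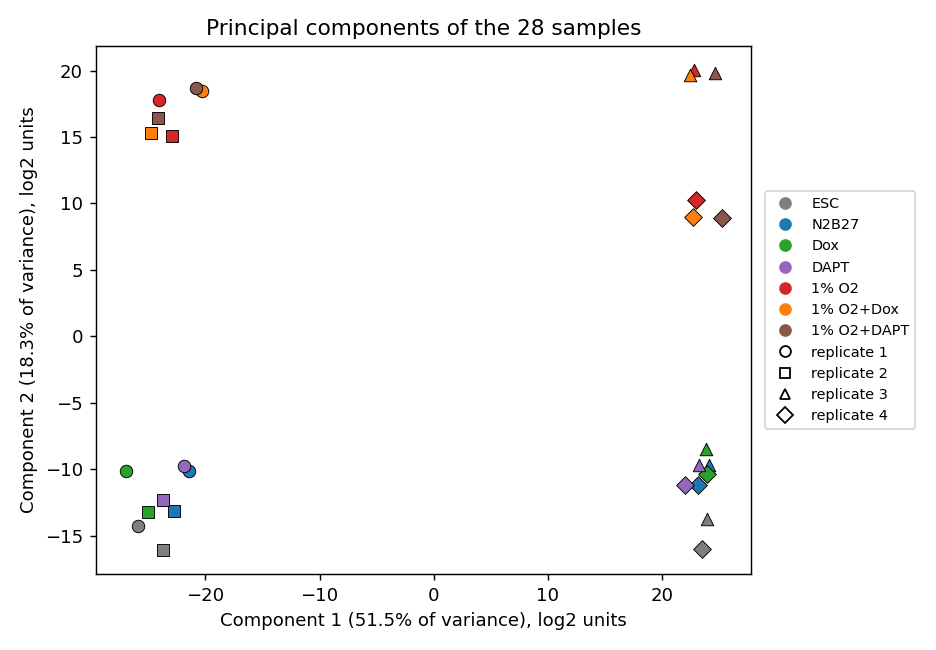
Principal components 1 and 2 (log2 units) of the 28 samples, coloured by group, with a marker shape for each replicate number. Component 1 (51.5% of variance) parts replicates 1 and 2 from replicates 3 and 4, and component 2 (18.3%) parts the 1% oxygen samples from the rest.

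The first comparison asked what the change from ES cell medium, which contains serum and LIF, to serum-free N2B27 did within 6 hours. As lists, genes that serum induces at once were lower in N2B27, and genes of the NRF2 response, which protects against oxidants and electrophiles, were higher. Among the falls were Edn1, the endothelin-1 precursor (log2 fold change -1.67 ± 0.34 SE), the matrix protein gene Ccn1 (-1.42 ± 0.24), the transferrin receptor gene Tfrc (-1.32 ± 0.24), the endothelial adhesion gene Esam (-1.25 ± 0.19), Aire (-1.11 ± 0.21), Slamf9 (-1.01 ± 0.15) and the protease gene Htra1 (adjusted p = 0.000132). Nppb, the precursor of brain natriuretic peptide, was at least 2.47-fold lower, with 0 of 4 N2B27 samples above background. Among the rises were the germline kinase gene Aurkc (1.35 ± 0.18), the carbonyl reductase gene Cbr3 (1.28 ± 0.13), the axonemal dynein gene Dnaic1 (0.96 ± 0.21), Hoxb5 (0.90 ± 0.21), Sgsm1 (0.87 ± 0.17) and the germ cell gene Tex19.2 (0.86 ± 0.19). Vstm4 was at least 1.72-fold higher, with 0 of 4 ESC samples above background. Plekha6 also passed the test (adjusted p = 0.0158) but lay above background on 1 of 4 N2B27 and 0 of 4 ESC samples, so no change is given.

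In all, 190 of 9809 genes changed, 120 higher and 70 lower in N2B27 (limma, adjusted p under 0.05, n = 4 per group). With the replicate block 1575 changed, 821 higher and 754 lower, including each of the 190. Within replicates 1 and 2 alone 33 genes changed, within replicates 3 and 4 alone 114, and 12 in both. All 29 named genes that passed had the same sign in both replicate sets. For the largest rises and falls the naming rule fixed this in advance. It took only genes with every sample of one group above every sample of the other. Leaving out 1 sample lowered the count to 120 (without ESC replicate 3), 123 (without ESC replicate 4) or 126 (without N2B27 replicate 4).

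Camera called 16 of the 30 lists in this comparison. Of the 8 that fell, serum immediate early genes had 2 of 15 members lower (3 adjusted over the list alone), with a median of -0.39 and an adjusted p of 3.86e-06. Ccn1 and Ccn2 (-0.81 ± 0.18) were the members that fell. LIF and STAT3 targets fell as a list (median -0.23, adjusted p = 0.000612) with 0 of 17 members changed one by one and 1 adjusted over the list alone. Both lists kept their calls with an estimated correlation (adjusted p = 0.0167 and 0.00455). Genes of SRF and the actin cytoskeleton had a median of -0.37 and 1 of 18 members lower, Vcl, which encodes vinculin (-0.48 ± 0.11). The list's adjusted p was 0.000985, and 0.386 with an estimated correlation, while 13 members fell with the block. The other falling lists were called at the preset correlation only. Their adjusted p with an estimated correlation was 0.289 for BMP and Id targets (0.0440 at the preset value; 1 of 9 lower), 0.0854 for FGF and ERK targets (0.0414; 1 of 12), 0.276 for mesoderm and primitive streak markers (0.0395; 1 of 14), 0.386 for trophectoderm markers (0.0414; 1 of 13) and 0.345 for endoplasmic reticulum chaperones (0.0447; 0 of 14). The changed members were Gata2 (-0.57 ± 0.15), which belongs to both the BMP and the trophectoderm list, Phlda1 (-0.46 ± 0.12) of the FGF list and Tal1 (-0.55 ± 0.14) of the mesoderm list.

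Of the 8 lists that rose, NRF2 and metal response genes had 5 of 15 members higher (6 adjusted over the list alone), a median of 0.29 and an adjusted p of 1.58e-06 (0.00455 with an estimated correlation). The quinone reductase gene Nqo1 rose by 0.86 ± 0.22, the sulfiredoxin gene Srxn1 by 0.80 ± 0.08 and the metallothionein gene Mt2 by 0.70 ± 0.18. A second Nqo1 probe gave 0.29. G2 and mitosis genes had positive values in 16 of 16 members (median 0.20, adjusted p = 0.000985, and 0.00966 with an estimated correlation), of which 0 passed one by one. The rest lost their calls with an estimated correlation. These were cholesterol synthesis and uptake (median 0.26, adjusted p = 0.00160, and 0.386 with an estimated correlation; Hsd17b7 0.51 ± 0.11, 1 of 18 members), fatty acid synthesis and desaturation (0.16, 0.00451, and 0.0695; 2 of 11 members, the desaturase genes Scd1 at 0.83 ± 0.20 and Scd2 at 0.78 ± 0.20), retinoic acid targets (0.31, 0.0106, and 0.341; 0 of 15), p53 targets (0.13, 0.0308, and 0.240; Ddit4l 0.55 ± 0.10, 1 of 19), S phase genes (0.08, 0.0308, and 0.0660; 0 of 19) and the integrated stress response (0.10, 0.0462, and 0.341; Nupr1 0.76 ± 0.17, 1 of 22). With the block the fatty acid list kept its call with an estimated correlation too (adjusted p = 0.0485), as did the SRF and actin list (0.00175), and Nodal and activin targets were called as lower (0.0475). Pluripotency genes were not called, and Pou5f1 (-0.11 ± 0.30; lower in 4 of 4 pairs, blocked adjusted p = 0.304) and Nanog (-0.02 ± 0.13) did not pass.

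Samples were left out in the model without the block, so a lost call may also come from unbalanced replicate sets. Leaving out 1 sample ended the calls of 13 of the 29 named genes. Their highest adjusted p on leaving out the sample named was 0.138 for Tal1 (ESC replicate 4), 0.168 for Gata2 (N2B27 replicate 4), 0.143 for Phlda1 and 0.185 for Mt2 (ESC replicate 1), 0.132 for Nqo1 and 0.0710 for Ccn2 (N2B27 replicate 2), 0.120 for Scd1, 0.107 for Hoxb5 and 0.0751 for Nupr1 (N2B27 replicate 3), 0.131 for Scd2 (N2B27 replicate 1), 0.0821 for Vcl (ESC replicate 3), 0.0590 for Dnaic1 (N2B27 replicate 4) and 0.0689 for Plekha6 (ESC replicate 1). The omissions that ended a call numbered 8 of 8 for Tal1 and Gata2, 7 for Nqo1, and 6 for Phlda1, Mt2, Scd1 and Scd2. They numbered 5 for Hoxb5, 3 for Vcl and Plekha6, and 2 for Ccn2, Nupr1 and Dnaic1. All 13 genes kept their calls with the block. Median scaling ended the calls of Gata2 (adjusted p = 0.115), Mt2 (0.127), Phlda1 (0.0902), Scd1 (0.0595), Tal1 (0.0552) and Vcl (0.0612). Of the 16 list calls 10 ended on leaving out 1 sample, with a highest adjusted p of 0.216 for the BMP and 0.204 for the trophectoderm list (N2B27 replicate 4), 0.206 for the stress response (N2B27 replicate 3), 0.168 for the chaperones (ESC replicate 2), 0.157 for mesoderm and 0.104 for SRF and actin (ESC replicate 1), 0.0753 for FGF (N2B27 replicate 2), 0.0710 for S phase and 0.0559 for retinoic acid (N2B27 replicate 1) and 0.0705 for p53 (ESC replicate 3). The stress response call ended on 6 of 8 omissions, and the BMP and FGF calls on 5. Those of the chaperones, mesoderm and trophectoderm ended on 4, of p53 and retinoic acid on 2, and of SRF and S phase on 1.

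The next comparison asked which genes doxycycline changed in N2B27 at ambient oxygen. The Notch1 probe rose by 0.66 ± 0.14, from 9.57 ± 0.21 to 10.23 ± 0.18 (log2 level, mean ± SD, n = 4). Whether this probe lies inside the part of Notch1 that doxycycline induces is not known here, so it does not check the induction. The 3 largest rises were members of the Notch target list. Nrarp, a feedback inhibitor of Notch, rose by 3.45 ± 0.29 from 7.97 ± 0.31 to 11.42 ± 0.71, and the repressor gene Hes5 by 2.93 ± 0.22 from 5.80 ± 0.38, where 1 of 4 N2B27 samples lay above background, to 8.73 ± 0.46. The transcription factor gene Sox9 rose by 2.27 ± 0.20, and the repressor genes Hey1 and Hes1 by 1.67 ± 0.21 and 0.72 ± 0.12. Other large rises were Trh, which encodes thyrotropin-releasing hormone (1.75 ± 0.35), Id4, an inhibitor of bHLH factors (1.65 ± 0.30; 1 of 4 N2B27 samples above background), the adhesion gene Cntnap2 (1.59 ± 0.21) and the ephrin gene Efna1 (1.58 ± 0.25).

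Of the named falls, the neuroendocrine factor gene Insm1 was at least 1.78-fold lower, with 0 of 4 Dox samples above background. The POU factor gene Pou3f1 fell by 0.84 on the log2 scale (SE 0.18), Gbx2, a homeobox gene of the pluripotency and LIF lists, by 0.70 (SE 0.09), and the bHLH gene Tal2 by 0.56 (SE 0.11). The others named were Ccdc160 (-0.81 ± 0.08), Sertad4 (-0.73 ± 0.16), Ccno (-0.67 ± 0.15) and Sertad1 (-0.50 ± 0.10).

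Doxycycline changed 33 of 9809 genes, 22 higher and 11 lower. The block gave 170, of which 100 were higher and 70 lower, and included each of the 33. Replicates 1 and 2 alone gave 8 genes and replicates 3 and 4 alone 21, with 3 in both. The signs were the same in both sets for all 19 named genes that passed, which the naming rule fixed in advance for the largest rises and falls. Without Dox replicate 1 the count was 18, and without N2B27 replicate 4 it was 21. Canonical Notch targets had 6 of 17 members higher (7 adjusted over the list alone), namely Nrarp, Hes5, Sox9, Hey1, Hes1 and Notch1 itself. The Notch1 probe may read the induced gene, so its rise need not be a response, and the list test includes it. Because the members not called moved little, the list's median was 0.04 and its mean 0.73, with an adjusted p by camera of 1.50e-25 (1.56e-05 with an estimated correlation). BMP and Id targets were also called as higher (adjusted p = 0.00211) on 1 of 9 members, Id4, and this call ended with an estimated correlation (adjusted p = 0.0847) and without Dox replicate 1 (0.0743). Of the HIF targets 1 of 35 rose, the glucose transporter gene Slc2a1 (0.80 ± 0.09), and the list was not called (adjusted p = 0.990). Notch pathway components had 1 of 23 members higher and no list call (0.310). With the block, camera also called cholesterol synthesis and uptake (adjusted p = 0.0267) and fibroblast markers (0.0267) as higher, and LIF and STAT3 targets (0.00749) and Wnt targets (0.0206) as lower. With an estimated correlation in the blocked model these were 0.624, 0.292, 0.0343 and 0.0444, so the first 2 calls were lost. Nanog (0.20 ± 0.13; higher in 4 of 4 pairs, blocked adjusted p = 0.268), Pou5f1 (0.13 ± 0.30), Vegfa (0.04 ± 0.17), Egln3 (0.11 ± 0.23) and Car9 (0.16 ± 0.14) did not pass.

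Of the 19 named calls, 7 ended on leaving out 1 sample, with a highest adjusted p of 0.281 for Sertad4 (Dox replicate 2), 0.223 for Ccno, 0.129 for Tal2 and 0.123 for Trh (N2B27 replicate 4), 0.209 for Pou3f1 and 0.184 for Notch1 (N2B27 replicate 1) and 0.127 for Sertad1 (Dox replicate 4). Of 8 omissions, 7 ended the calls of Sertad4 and Ccno and 6 those of Notch1 and Sertad1. The call of Pou3f1 ended on 5, and those of Tal2 and Trh on 4. With the block all 19 were called. Median scaling ended the calls of Notch1 (adjusted p = 0.0913), Pou3f1 (0.0570), Sertad1 (0.0579) and Sertad4 (0.0876).

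**Figure D2:**
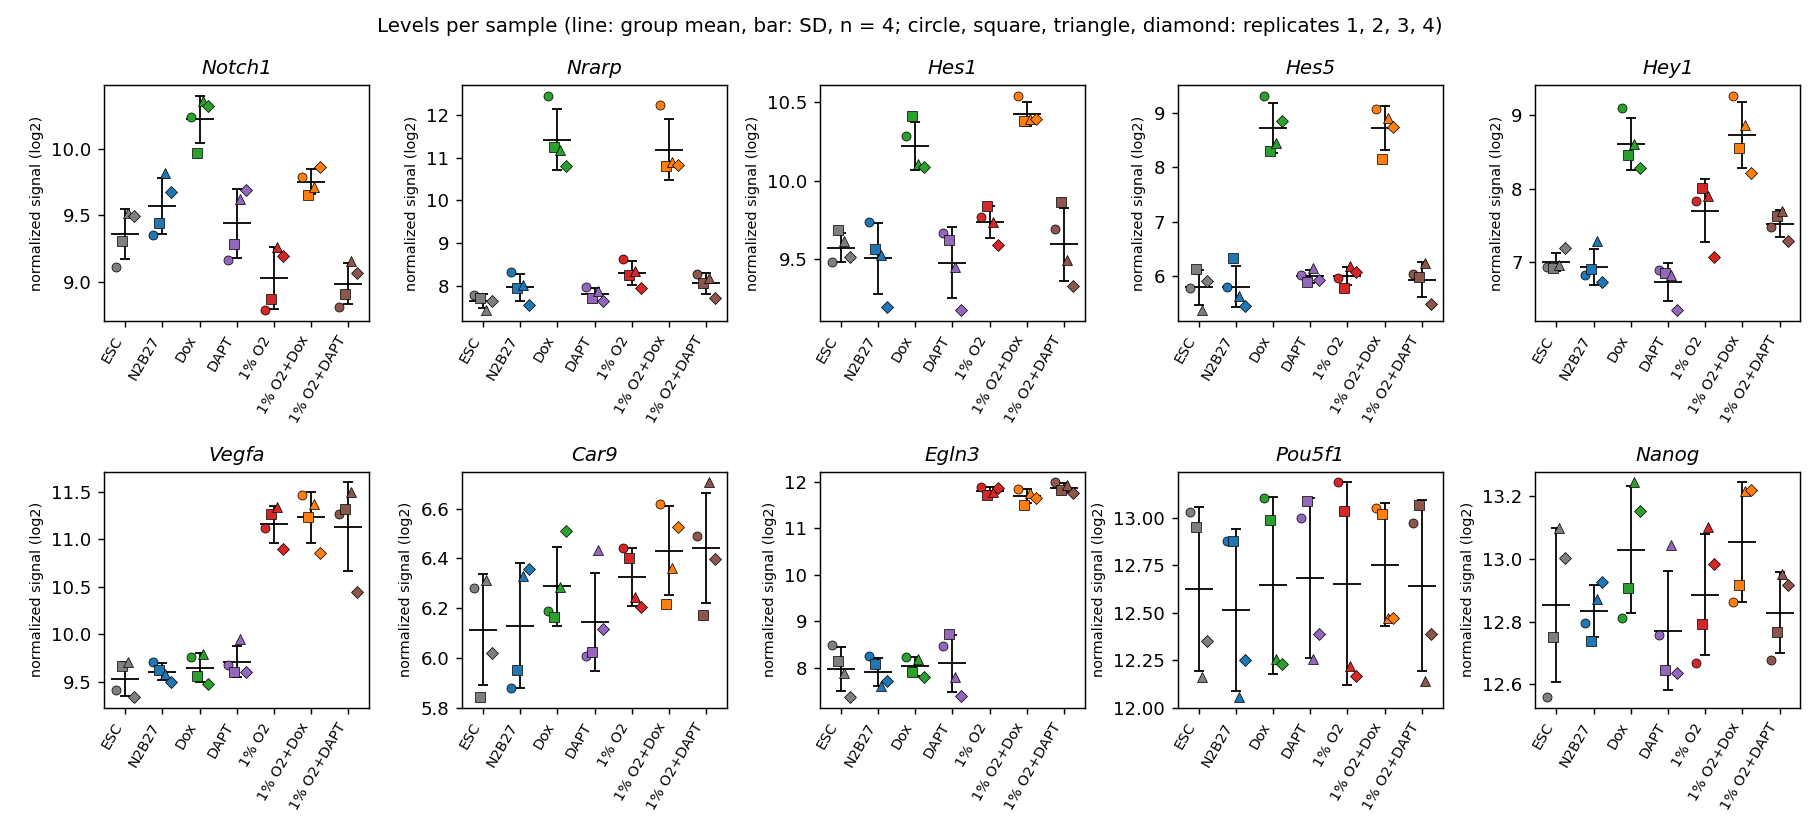
Normalized log2 signal of the 10 genes named in any case in each of the 7 groups, with a marker per sample (circle, square, triangle and diamond for replicates 1 to 4), the group mean as a line and the SD as a bar (n = 4). Nrarp rose from a mean of 7.97 in N2B27 to 11.42 with Dox, and Egln3 from 7.91 in N2B27 to 11.81 under 1% oxygen.

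DAPT at ambient oxygen was compared with N2B27 to ask what the signaling already present in these cells contributes. The dose of 2.5 ng/ml is known only from the labels, and the absence of calls does not by itself tell an inactive dose from signaling without effect. No known Notch target was called with DAPT. The differences were -0.16 ± 0.29 for Nrarp, -0.21 ± 0.21 for Hey1, -0.03 ± 0.12 for Hes1 and -0.13 ± 0.14 for Notch1, and Hes5 was above background on 1 of 4 N2B27 and 0 of 4 DAPT samples. Pou5f1 (0.17 ± 0.30), Nanog (-0.06 ± 0.13), Vegfa (0.10 ± 0.17), Egln3 (0.18 ± 0.23) and Car9 (0.02 ± 0.14) did not pass. Pou5f1 was higher in 4 of 4 pairs (blocked adjusted p = 0.836). No gene was called by limma, with 0 of 9809 in the main model and 0 with the block. At an unadjusted p under 0.05 the counts were 82 and 560, against 490 by chance. The model without the block keeps the spread between replicate numbers in its errors, so its counts run low. For Dox against N2B27 it gave 228 such genes although 33 were called. Only the blocked count is fairly set against 490. The authors' processed values gave 1 call, Plaat3 (-0.29, adjusted p = 0.00233), named after its values were seen. Canonical Notch targets had a median of -0.02. Of the lists, camera called cholesterol synthesis and uptake as higher (median 0.10, 16 of 18 members positive, 0 changed one by one, adjusted p = 0.0409, and 0.994 with an estimated correlation), and leaving out N2B27 replicate 4 raised its adjusted p to 0.740. The call of this list ended on 5 of 8 omissions. Only with the block were HIF targets (0.0416) and endoplasmic reticulum chaperones (0.00459) called as higher and Nodal and activin targets (0.0197) as lower, each lost with an estimated correlation (adjusted p of 0.917, 0.562 and 0.400 in the blocked model).

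The response to low oxygen was measured as 1% O2 against N2B27. Targets of the hypoxia-inducible factors (HIF) and glycolytic genes rose together. Stc1, which encodes stanniocalcin 1, was at least 12.9-fold higher, with 0 of 4 N2B27 samples above background. The vasoactive peptide gene Adm rose by 4.60 ± 0.22, or 24.2-fold, and Egln3, a prolyl hydroxylase that marks HIF for degradation, rose by 3.90 ± 0.23, from 7.91 ± 0.30 to 11.81 ± 0.08 (log2 level, mean ± SD, n = 4). Ndrg1 (3.86 ± 0.32), Ier3 (3.57 ± 0.29), Ankrd37 (3.25 ± 0.22), Aire (3.20 ± 0.21) and the amine oxidase gene Aoc3 (3.02 ± 0.22) followed, and a second Ndrg1 probe gave 3.93. Vegfa, the vascular growth factor gene, rose by 1.55 ± 0.17. Falls were smaller. The fucosyltransferase gene Fut4 changed by -0.91 ± 0.12, Csf2ra by -0.82 ± 0.18, Bcas1 by -0.82 ± 0.23, Ifnlr1 by -0.80 ± 0.15, the titin gene Ttn by -0.76 ± 0.12, Tril by -0.75 ± 0.20, Mlana by -0.73 ± 0.17 and the innate immune receptor gene Tlr2 by -0.72 ± 0.16. The second Ifnlr1 probe gave 0.02, so this fall rests on 1 probe.

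In this comparison 404 genes changed, 278 higher and 126 lower, and with the block 1958 changed, 899 higher and 1059 lower, including each of the 404. Median scaling lowered the share of higher calls from 68.8% to 58.5%. Replicates 1 and 2 alone gave 318 genes, replicates 3 and 4 alone 166, and 105 were in both. Without 1% O2 replicate 3 the count was 260. Of the HIF targets 27 of 35 rose (29 adjusted over the list alone), with a median of 1.55, which was 1.56 in replicates 1 and 2 and 1.58 in replicates 3 and 4 (adjusted p = 1.53e-77, and 1.77e-06 with an estimated correlation). Glycolysis had 10 of 17 members higher, also adjusted over the list alone (median 0.69, adjusted p = 8.64e-19, and 1.93e-05 with an estimated correlation), among them Pgm1 (2.40 ± 0.14), Aldoc (1.88 ± 0.20) and Pfkp (1.49 ± 0.32). Neural progenitor and neuron markers rose as a list (2 of 12 members, 3 adjusted over the list alone, median 0.32, adjusted p = 2.03e-05, and 0.0155 with an estimated correlation, or 0.0533 in the blocked model) through the homeobox gene Otx2 (1.33 ± 0.17), which also marks the epiblast, and the neuronal gene Elavl3 (0.93 ± 0.12). Cholesterol synthesis and uptake was called as higher (median 0.32, adjusted p = 4.87e-05) with 0 of 18 members changed, 5 adjusted over the list alone and 13 with the block, and its adjusted p was 0.381 with an estimated correlation. NRF2 and metal response genes were not called as a list (median -0.17, adjusted p = 0.987), but 3 of 15 rose and 2 fell, with Mt1 at 0.81 ± 0.12, Mt2 at 0.67 ± 0.18 and the heme oxygenase gene Hmox1 at 0.58 ± 0.12. With the block camera added JmjC histone demethylases (adjusted p = 0.00848), fatty acid synthesis (0.00894), Wnt targets (0.0136), retinoic acid targets (0.0330) and markers of endoderm (0.00969), trophectoderm (0.0330) and fibroblasts (0.0422), all as higher. Each of these 7 lost its call with an estimated correlation in the blocked model (adjusted p from 0.0516 for the JmjC and Wnt lists to 0.238 for the retinoic acid and fibroblast lists).

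Low oxygen also moved part of the Notch gene set without doxycycline. Of 17 canonical Notch targets 3 rose, Sox9 (0.99 ± 0.20), Hey1 (0.76 ± 0.21) and the ubiquitin ligase gene Dtx1 (0.65 ± 0.15), and Notch1 fell by 0.54 on the log2 scale (SE 0.14), from 9.57 ± 0.21 to 9.03 ± 0.24. The list was not called (adjusted p = 0.131). Hes5 lay above background on 1 of 4 samples of each group. Nrarp (0.33 ± 0.29) and Hes1 (0.23 ± 0.12, adjusted p = 0.433) did not pass, and Hes1 did with the block (adjusted p = 0.0430). Nrarp was nevertheless higher under 1% oxygen in every replicate number. Its log2 levels went from 8.32 to 8.62, 7.96 to 8.26, 8.03 to 8.35 and 7.56 to 7.95. Car9, a carbonic anhydrase gene and common hypoxia marker, did not pass at the probe used (0.19 ± 0.14), which lay above background on 2 of 4 N2B27 and 3 of 4 1% O2 samples, and a second, dimmer probe gave 0.87. Pou5f1 (0.14 ± 0.30) and Nanog (0.05 ± 0.13) did not pass. All 29 named genes that passed had the same sign in both replicate sets, which the naming rule fixed in advance for the largest rises and falls. All 29 were called with the block, and 7 of them lost their call on leaving out 1 sample. These were Bcas1 and Tril (highest adjusted p 0.178 and 0.125) and Notch1 (0.103), each without 1% O2 replicate 1, Hey1 (0.147), Mt2 (0.156) and Dtx1 (0.0746) without 1% O2 replicate 3, and Mlana (0.0538) without N2B27 replicate 2. The call of Bcas1 ended on 7 of 8 omissions, of Hey1 on 6, and of Tril and Mt2 on 5. That of Notch1 ended on 4, of Dtx1 on 2 and of Mlana on 1. Median scaling ended the calls of Hey1 (adjusted p = 0.0545) and Mt2 (0.138).

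**Figure D3:**
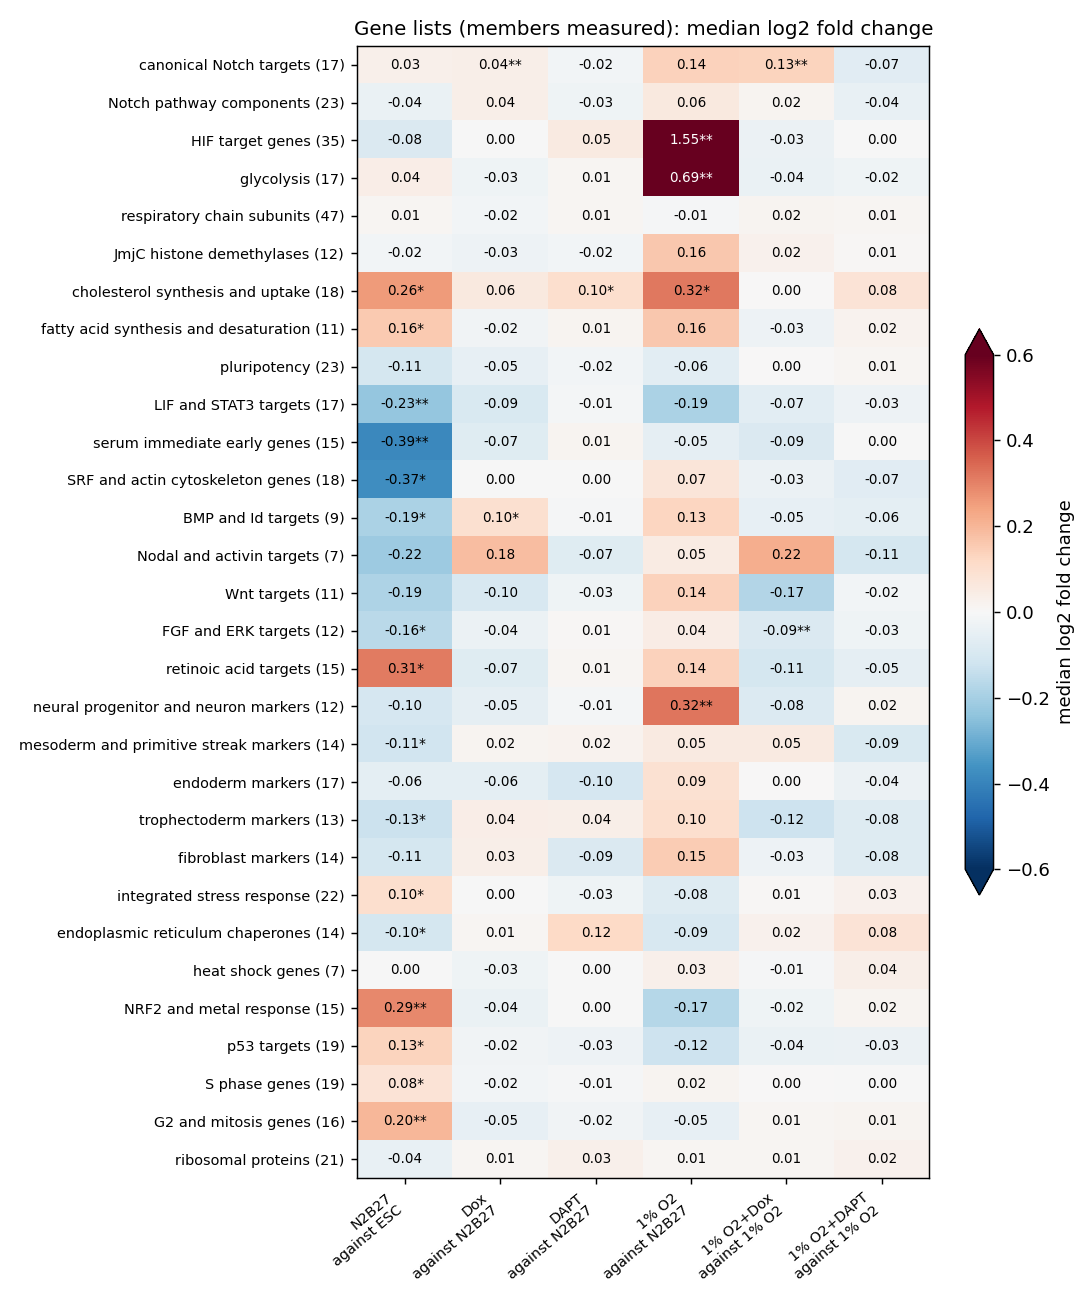
Median log2 fold change of the 30 gene lists (number of measured members in brackets) in the 6 main comparisons, with colours from -0.6 to 0.6. An asterisk marks an adjusted p under 0.05 by camera at the preset correlation, and a pair of asterisks one that holds with an estimated correlation as well. HIF targets (1.55) and glycolysis (0.69) under 1% oxygen have the highest medians.

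Doxycycline under 1% oxygen was compared with 1% O2 alone to see which responses to doxycycline remain in low oxygen. The leading genes were those of ambient oxygen. Nrarp rose by 2.89 ± 0.29 to 11.19 ± 0.70, Hes5 by 2.73 ± 0.22 to 8.73 ± 0.40 (log2 level, mean ± SD, n = 4; 1 of 4 samples of 1% O2 alone above background), Sox9 by 1.68 ± 0.20, Id4 by 1.52 ± 0.30, Cntnap2 by 1.48 ± 0.21, Lrrn4 by 1.09 ± 0.19, Hey1 by 1.03 ± 0.21, Notch1 by 0.73 ± 0.14 and Hes1 by 0.69 ± 0.12. Higd1b was at least 1.76-fold higher, with 0 of 4 samples of 1% O2 alone above background. The falls were Insm1 (-1.26 ± 0.22; 1 of 4 treated samples above background), the bHLH genes Olig3 (-1.10 ± 0.22) and Tal2 (-0.81 ± 0.11), Ccno (-0.73 ± 0.15), Gbx2 (-0.58 ± 0.09), the podoplanin gene Pdpn (-0.46 ± 0.07) and Sbk1 (-0.45 ± 0.09). Vegfa (0.08 ± 0.17), Egln3 (-0.11 ± 0.23), Car9 (0.11 ± 0.14), Nanog (0.17 ± 0.13; higher in 4 of 4 pairs, blocked adjusted p = 0.394) and Pou5f1 (0.10 ± 0.30) did not pass.

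The count was 19 genes, 12 higher and 7 lower, and 143 with the block, 72 higher and 71 lower, including each of the 19. It was 7 within replicates 1 and 2, 8 within replicates 3 and 4 and 3 in both, 10 without 1% O2+Dox replicate 1, 11 without 1% O2 replicate 1, and 12 with median scaling. Canonical Notch targets again had 6 of 17 members higher (7 adjusted over the list alone; median 0.13, mean 0.59, adjusted p = 4.32e-21, and 6.49e-05 with an estimated correlation), the same 6 genes as at ambient oxygen, Notch1 included. FGF and ERK targets were lower as a list (median -0.09, 0 of 12 members changed, adjusted p = 0.0185, and 0.0400 with an estimated correlation), and this call ended without 1% O2+Dox replicate 2 (adjusted p = 0.251), 1% O2 replicate 1 or 1% O2 replicate 3. The block added LIF and STAT3 targets (adjusted p = 0.0337), Wnt targets (0.0309) and trophectoderm markers (0.0309), all lower and all lost with an estimated correlation in the blocked model (0.0780, 0.0780 and 0.242). All 17 named genes that passed had the same sign in both replicate sets, which the naming rule fixed in advance for the largest rises and falls. All 17 were called with the block. Leaving out 1 sample ended 10 of these calls, with a highest adjusted p of 0.266 for Hey1, 0.0526 for Hes1 and 0.0526 for Lrrn4 (1% O2+Dox replicate 1), 0.197 for Olig3, 0.101 for Notch1 and 0.0531 for Insm1 (1% O2 replicate 1), 0.138 for Id4 and 0.0662 for Higd1b (1% O2 replicate 4), 0.159 for Ccno (1% O2+Dox replicate 3) and 0.112 for Sbk1 (1% O2+Dox replicate 4). The call of Ccno ended on 7 of 8 omissions, and those of Hey1, Olig3 and Id4 on 6. Those of Notch1 and Sbk1 ended on 4, of Higd1b on 2, and of Hes1, Lrrn4 and Insm1 on 1. Median scaling ended the calls of Ccno (adjusted p = 0.0544), Gbx2 (0.0598), Hey1 (0.0703), Notch1 (0.0613), Olig3 (0.0703) and Sbk1 (0.152).

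The Dox effects at both oxygen levels come from separate samples and were compared across genes, which are not independent replicates. Pearson's r was 0.51 and Spearman's rho 0.25 over 9809 genes. Within replicates 1 and 2 r was 0.31, and within replicates 3 and 4 it was 0.41. Of the 33 genes changed at ambient oxygen all 33 had the same sign under 1% oxygen, 11 were higher in both and 6 lower in both, where independent lists would share 0.0269 and 0.00785. The difference between the effects was tested as an interaction. A single gene was called, Slc2a1 (-0.79 ± 0.13, adjusted p = 0.0395), which doxycycline raised by 0.80 ± 0.09 at ambient oxygen and which stood at 14.63 with and without it under 1% oxygen. Its sign was the same in 4 of 4 replicate numbers and the block gave an adjusted p of 0.000935. Leaving out 1 sample ended the call in 14 of 16 cases, with a highest adjusted p of 0.163 without Dox replicate 1, and median scaling raised it to 0.523. Over the 16 other alternatives its adjusted p ran from 0.000935 to 1.00. With the block 2 genes were called, Slc2a1 and Ccdc160 (0.54 ± 0.12, blocked adjusted p = 0.0266), the latter chosen after its values were seen. At an unadjusted p under 0.05 there were 57 genes in the main model, whose counts run low, and 398 with the block, against 490 by chance. The interactions of Nrarp (-0.56 ± 0.41), Hey1 (-0.64 ± 0.30), Hes5 (-0.20 ± 0.32, with both control groups near background), Hes1 (-0.03 ± 0.17) and Notch1 (0.07 ± 0.20) did not pass, and camera called no list.

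**Figure D4:**
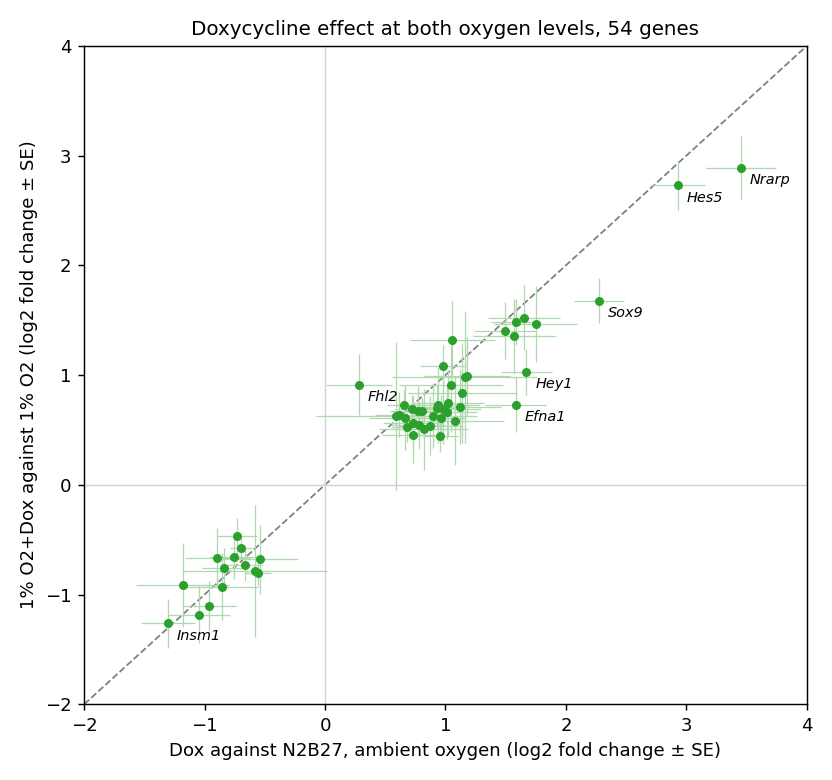
Log2 fold change of doxycycline at ambient oxygen (horizontal) and under 1% oxygen (vertical), each with its SE, for the 54 genes called with the block when the effect is averaged over both oxygen levels and changed at least 1.5-fold on average. The dashed line marks equal effects, and 41 of the 54 points lie nearer to 0 on the vertical axis than on the horizontal one.

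DAPT under 1% oxygen was compared with 1% O2 alone. As at ambient oxygen no gene was called, with 0 of 9809 in the main model and 0 with the block. At an unadjusted p under 0.05 the main model, whose counts run low, gave 105 genes and the block 594, against 490 by chance. Nrarp differed by -0.24 ± 0.29, Hey1 by -0.18 ± 0.21, Hes1 by -0.14 ± 0.12 and Notch1 by -0.04 ± 0.14. Nrarp was lower in 4 of 4 pairs here and in 3 of 4 at ambient oxygen, with a blocked adjusted p of 0.916 and 0.957. Hes5 lay above background on 1 of 4 samples of each group, so a fall could not be seen. Egln3 (0.07 ± 0.23), Vegfa (-0.03 ± 0.17), Car9 (0.12 ± 0.14), Pou5f1 (-0.01 ± 0.30) and Nanog (-0.06 ± 0.13) did not pass either. Canonical Notch targets had a median of -0.07. Camera called no list, and with the block it called cholesterol synthesis and uptake (adjusted p = 0.00131), the integrated stress response (0.0347) and endoplasmic reticulum chaperones (0.000234) as higher and Nodal and activin targets (0.0164) as lower. With an estimated correlation in the blocked model these were 0.370, 0.302, 0.184 and 0.184. The interaction of DAPT with oxygen also gave 0 genes with and without the block, 58 and 418 at an unadjusted p under 0.05, and no list. Across genes the DAPT effects at both oxygen levels correlated at r = 0.13 (rho 0.11).

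The oxygen response was measured again in the presence of doxycycline and of DAPT, to see whether either changes it. Its main genes were those of N2B27 alone. With doxycycline Adm was at least 21.8-fold and Stc1 at least 12.8-fold higher, both with 0 of 4 Dox samples above background, and Ndrg1 rose by 3.72 ± 0.32, Egln3 by 3.68 ± 0.23, Ankrd37 by 3.61 ± 0.22, Ier3 by 3.40 ± 0.29 and Vegfa by 1.58 ± 0.17. With DAPT Stc1 was at least 12.5-fold higher, and Adm rose by 4.45 ± 0.22, Egln3 by 3.79 ± 0.23, Ndrg1 by 3.74 ± 0.32, Ier3 by 3.46 ± 0.29, Ankrd37 by 3.21 ± 0.22 and Vegfa by 1.42 ± 0.17. Hey1 differed by 0.12 ± 0.21 with doxycycline, and with DAPT it rose by 0.80 ± 0.21, a call that ended without DAPT replicate 4 (adjusted p = 0.119). Notch1 was -0.47 ± 0.14 and -0.45 ± 0.14 (adjusted p = 0.0544 and 0.0653), and the block called both (9.50e-05 and 0.000147). Car9 differed by 0.14 ± 0.14 and 0.30 ± 0.14 at the probe used, and by 1.21 and 0.67 at its second probe.

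With doxycycline 399 genes changed between oxygen levels, 260 higher and 139 lower under 1% oxygen (block 1911, 895 higher and 1016 lower), and 368 and 115 within replicates 1 and 2 and replicates 3 and 4. With DAPT 396 changed, 264 higher and 132 lower (block 2059, 920 higher and 1139 lower), and 404 and 142 within the replicate sets. Median scaling moved the median of all genes to -0.12 in the DAPT contrast (-0.02 in the main model). Tested against 0, and so with that shift included, it gave 833 genes, 195 higher and 638 lower. HIF targets had 27 of 35 (29 adjusted over the list alone) and 28 of 35 (30) members higher, with adjusted p of 1.60e-75 and 4.05e-74, and glycolysis 10 of 17 (10) and 9 of 17 (11), with 6.35e-18 and 6.01e-17. Neural progenitor and neuron markers were higher in both (3 and 2 of 12 members, adjusted p = 0.000263 and 6.66e-06). These 3 lists kept their calls with an estimated correlation, at most at an adjusted p of 0.0415. Cholesterol synthesis and uptake (0.00379 and 9.68e-05) and endoderm markers (0.00410 and 0.0235) did not, with 0.638 and 0.418 and with 0.0522 and 0.171 on an estimated correlation. With doxycycline JmjC histone demethylases were called (0.0298, and 0.0522 with an estimated correlation), and with DAPT the integrated stress response (0.0403, and 0.374), which the block ended (0.0586). Leaving out 1 sample raised the adjusted p of the stress response to 0.144 (DAPT replicate 2), of the endoderm list with DAPT to 0.0581 (DAPT replicate 4), of the JmjC list to 0.0595 (1% O2+Dox replicate 4) and of the cholesterol list with doxycycline to 0.0523 (1% O2+Dox replicate 2). The stress response call ended on 4 of 8 omissions, the endoderm and JmjC calls on 2 and the cholesterol call on 1. The block added Wnt targets in both (0.0140 and 0.0195, and 0.0446 and 0.0607 with an estimated correlation) and fatty acid synthesis with DAPT (0.00432, and 0.0903). Across genes the oxygen effect in N2B27 correlated at r = 0.87 with that under doxycycline and at 0.87 with that under DAPT. Of its 404 calls, 218 were higher and 71 lower in both N2B27 and Dox, where independent lists would share 7.37 and 1.79, and 229 and 66 in both N2B27 and DAPT, against 7.48 and 1.70.

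Contrasts against the same N2B27 samples share the chance values of those samples. The Dox and 1% O2 effects correlated at r = 0.129 (covariance 0.00574), while simulated unchanged groups against the same controls gave a mean r of 0.499 and a covariance of 0.00571. With the N2B27 samples split between the contrasts r lay between -0.0117 and 0.0147. Genes higher in both numbered 5, against 0.624 for independent lists, and 1 was lower in both, against 0.141, while 1 was higher with Dox and lower under 1% O2, against 0.283, and 1 the other way round, against 0.312. Independent lists leave out the shared controls. For Dox and DAPT r was 0.326 (covariance 0.00553), and with split controls between -0.0238 and 0.0465. Both covariances lay within the range of the simulations (0.00520 to 0.00704), which shared controls alone produce.

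Of the 30 lists, 8 were called in none of the 10 contrasts by the main model. They were Notch pathway components, respiratory chain subunits, pluripotency, Nodal and activin targets, Wnt targets, fibroblast markers, heat shock genes and ribosomal proteins. Their medians lay between -0.22 and 0.22, and the lowest adjusted p was 0.0776, for pluripotency genes with doxycycline.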

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

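The tests in this part were fixed before their results were seen, except where stated. Of 84 groups of values examined, 70 of them gene levels, 5 held a sample far from the others, where chance gives 4.2. Of these samples 1% O2+Dox replicate 1 was highest for Hes1 (10.54, others 10.38 to 10.39) and for Nrarp (12.24, others 10.79 to 10.90), ESC replicate 4 was highest for Hey1 (7.19, others 6.91 to 6.95), and DAPT replicate 4 was lowest for Hey1 (6.34, others 6.82 to 6.89). In the Dox group at ambient oxygen Nrarp was highest in replicate 1 too (12.45, others 10.80 to 11.25). Hes1 was highest there in replicate 2 (10.41, replicate 1 at 10.29). On the array of 1% O2+DAPT replicate 2, 47.7% of probes lay above background, against 49.4% to 49.6% on the other arrays of that group. Without 1% O2+Dox replicate 1 doxycycline changed 10 genes under 1% oxygen in place of 19, and the rise of Hey1 between oxygen levels with DAPT was no longer called without DAPT replicate 4 (adjusted p = 0.119), nor without any of 4 other samples of the 8.

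Slc2a1 was the gene whose doxycycline effect differed between oxygen levels, by -0.79 on the log2 scale. Among 100 regroupings of the residuals, the real one included, 1 called as many genes, the real one (1 gene, highest other 0). These regroupings do not keep the replicate numbers together, so they are not a fair comparison for the paired samples and chance is not judged from them. The call ended under 9 of 16 alternatives other than leaving out a sample, with the same sign in all 16, and on leaving out any of 14 of the 16 samples. For DAPT the real count was 0, so all 100 of 100 regroupings had as many genes by necessity, and this says nothing on chance. The highest other count was 3251. A regrouping that calls 3251 genes points to a structure of the samples. The only 2 of the 100 in which replicates 1 and 2 came near to lining up with the interaction (a difference of counts of 6, where 8 is complete) were those that called 3251 and 3220 genes, and the others called at most 25.

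Probes without a gene name were left out of the comparisons. Of 1659 such probes that passed the same filter, 6 were called for N2B27 against ESC (2 higher), 1 for Dox against N2B27 (higher), 36 for 1% O2 against N2B27 (26 higher), 27 for 1% O2+Dox against Dox (20 higher) and 34 for 1% O2+DAPT against DAPT (27 higher). They were not assigned to transcripts here.

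The pattern weighed first is the gap between replicates 1 and 2 and replicates 3 and 4, in which 3350 of 9809 genes were higher and 3535 lower in replicates 3 and 4. Stra8 (2.64) and Sox2 (1.95) were higher and Crebbp (-4.76) lower in replicates 3 and 4, all chosen after their values were seen. An effect of the array on single probes may be the source, since the gap correlated at only 0.144 between the brightest and second probe of 1946 genes, where the 1% O2 effect correlated at 0.753, and 48.2% of 110 genes at least 2-fold apart had the same sign at both probes. A dependence on signal level is argued against by the share of variance that a smooth curve takes, -0.00216 after quantile normalization, which itself removes such a trend, and 0.00423 on signals not normalized between arrays, where 7675 genes differed. The latter share was computed after the former was seen. Replicates 1 and 2 had fewer probes above background, 48.5% (SD 0.587, 14 arrays) against 49.3% (SD 0.387, 16 arrays), a difference of 0.803 percentage points. Their ranges overlap (47.7% to 49.6% and 48.7% to 49.9%), which had been set beforehand as evidence against a loss of signal, but overlap does not exclude a difference of means of this size. The background limit was higher in replicates 1 and 2 (34.4 to 41.6 signal units) than in replicates 3 and 4 (29.3 to 32.4). The share above it thus depends on the limit as well as on the signal. Median signal was 31.2 to 37.9 in replicates 1 and 2 and 27.3 to 31.5 in replicates 3 and 4. A loss of signal in replicates 1 and 2 would lower genes in those samples. On signals not normalized between arrays, however, the median gene was lower in replicates 3 and 4 (-0.255 on the log2 scale). That median argues against such a loss as the source of the whole gap. After normalization 3535 genes were lower and 3350 higher in replicates 3 and 4. Quantile normalization gives every array the same distribution and evens out such a loss, so these counts cannot decide it. Of the 30 lists, camera called SRF and actin genes on this gap (14 of 18 lower and 1 higher in replicates 3 and 4, median -0.53, adjusted p = 0.0134), and the call was lost with an estimated correlation (0.783). This test and the counts of genes above took the samples as independent, although samples of the same replicate number vary together. Both may therefore overstate the gap. The labels give no group that parts these sets, so no biological explanation was tested beyond these lists, and a difference between cultures stays open.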

How the results depend on the processing

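Alternatives chosen after seeing the data were the 2-level batch term, each replicate set alone, the normexp offset of 50 and effects averaged over both oxygen levels. Over all alternatives 0 of the 110 named calls and 0 of the 37 list calls reversed direction. Of the named calls 37 kept their side of the threshold in every alternative run, the omission of each sample included, and 39 lost it when some sample was left out. Of the list calls these were 15 and 17. Named calls lost were 59 with only the compared groups, 52 and 49 with replicates 1 and 2 or 3 and 4 alone, 21 without a filter, 21 with the authors' values, 19 with median scaling, 9 with every probe, 7 without background correction, 5 with cyclic loess, 4 with the offset of 50, 1 with a variance trend and 0 with the block, the batch term or array weights. Unless stated, the cause was not tested.

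Counts below are in the order N2B27 against ESC, Dox against N2B27, 1% O2 against N2B27, 1% O2+Dox against 1% O2, 1% O2+Dox against Dox and 1% O2+DAPT against DAPT, with 190, 33, 404, 19, 399 and 396 in the main model. The replicate block gave 1575, 170, 1958, 143, 1911 and 2059, and 2 for the Dox by oxygen interaction, because it removes the spread between replicate numbers. The 2-level batch term gave 713, 66, 1062, 37, 1073 and 1117. Only the groups of the comparison gave 14, 8, 175, 1, 140 and 140 with fewer samples to estimate the spread. A threshold of 0.01 gave 74, 17, 216, 11, 223 and 219, and a fold of at least 1.5 gave 80, 212, 199 and 210 for the comparisons it moved most (N2B27 against ESC, 1% O2 against N2B27 and the last pair). Replicates 1 and 2 alone gave 33, 8 and 7 for N2B27 against ESC, Dox against N2B27 and 1% O2+Dox against 1% O2, and replicates 3 and 4 alone gave 114, 21, 166, 8, 115 and 142, with fewer samples in each.

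Median scaling gave 12 genes for 1% O2+Dox against 1% O2 and 833 for 1% O2+DAPT against DAPT, where 23.4% were higher in place of 66.7% and the median of all genes moved to -0.12. It also changed the share of higher genes to 78.3% for Dox against N2B27 (66.7% in the main model) and to 58.5% for 1% O2 against N2B27 (68.8%). The authors' values gave 77.8% for Dox against N2B27 and 1 gene for DAPT against N2B27. No filter on dim probes gave 21 genes for Dox against N2B27, with more genes tested. Averaging over both oxygen levels gave 61 genes for Dox, and 356 with the block, and for DAPT with the block 1 gene, Lefty1. The interaction of Dox with oxygen fell from 1 gene to 0 with no background correction, median scaling, cyclic loess, the authors' values, no filter, every probe, only the groups of the comparison, a threshold of 0.01 and replicates 3 and 4 alone.

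List calls numbered 37 of 300, 61 with the block (25 added, 1 lost), 16 with camera at an estimated correlation and 34 with fry (14 lost, 11 gained; 7 calls for N2B27 against ESC, where camera made 16). The correlation of Dox effects between oxygen levels (0.512) was 0.966 over the 35 genes called in either, 0.309 in replicates 1 and 2 and 0.406 in replicates 3 and 4. With N2B27 controls split, the correlation of Dox with 1% O2 effects lay between -0.0117 and 0.0147 and of Dox with DAPT effects between -0.0238 and 0.0465.

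Leaving out 1 sample gave 120 to 148 genes for N2B27 against ESC, 18 to 27 for Dox against N2B27, 260 to 468 for 1% O2 against N2B27, 10 to 17 for 1% O2+Dox against 1% O2, 268 to 474 for 1% O2+Dox against Dox, 282 to 538 for 1% O2+DAPT against DAPT, 0 to 1 for the Dox by oxygen interaction, 0 to 0 for both DAPT comparisons and the DAPT by oxygen interaction, 30 to 45 list calls, and correlations of 0.370 to 0.504, 0.0890 to 0.294 and 0.190 to 0.585 for the Dox effects, Dox with 1% O2 and Dox with DAPT. Not run were normexp with detection p-values, which the tables lack, a slide block, as no slides are known, and every probe for lists. A stricter filter removed some named genes. Signal over background limits the dim genes, for which only a bound on the fold is given.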

Other observations

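Genes of several stress and chromatin lists rose under 1% oxygen although their lists were not called as a whole in the main model. The block called the JmjC list (adjusted p = 0.00848, and 0.0516 with an estimated correlation). They were chosen after their values were seen, and all are 1% O2 against N2B27. Of the integrated stress response 4 of 22 members rose, the mTOR inhibitor gene Ddit4 (2.38 ± 0.21), the lipoprotein receptor gene Vldlr (2.06 ± 0.24), both also HIF targets, Shmt2 (0.73 ± 0.13) and Ppp1r15a (0.50 ± 0.11). Of the immediate early genes 3 of 15 rose, Ier3, the phosphatase gene Dusp1 (1.52 ± 0.15) and Fos (1.43 ± 0.18), with a list median of -0.05 and an adjusted p of 0.0549. Of the JmjC histone demethylases 2 of 12 rose, Kdm4b (1.35 ± 0.20) and Kdm5b (0.61 ± 0.10), also at 0.0549 for the list. The pluripotency gene Klf2 rose by 0.73 ± 0.18 and the LIF list member Bcl3 fell by 0.49 on the log2 scale.

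Other splits of the 8 samples of each comparison were counted, 35 per comparison with the real one. In the main model 1 of 35, the real split, gave as many genes for N2B27 against ESC (190, highest other 0), Dox against N2B27 (33, 0), 1% O2 against N2B27 (404, 1), 1% O2+Dox against 1% O2 (19, 1), 1% O2+Dox against Dox (399, 0) and 1% O2+DAPT against DAPT (396, 1), with all splits taken as alike. The replicate numbers pair the samples, however, and the splits comparable to the real one are the 8 that part all 4 pairs, too few for a share under 0.05. Among these the highest other count in the main model was 0, and 1 for 1% O2+DAPT against DAPT. The other splits leave at least 1 pair together. For DAPT all 35 of 35 gave as many at both oxygen levels (real 0, highest other 0 and 1), which a real count of 0 makes certain. The split into replicates 1 and 2 against 3 and 4 called 0 genes in each, although 6885 genes differed between these sets over all samples. That gap stays in the spread of the main model, which therefore had little power to call genes in any other split. The low counts of the other splits in that model thus say little. With the block only those 8 splits were run. The real values and the highest others were 1575 and 0, 170 and 0, 1958 and 2, 143 and 0, 1911 and 15, and 2059 and 163 in the same order, with 1 split as large in each, and for DAPT 0 and 1 at ambient oxygen and 0 and 0 under 1% oxygen, with 8 of 8, again certain at a real count of 0.

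Genes that doxycycline moves most may move less under 1% oxygen. Among 54 genes called with the block for the effect averaged over both oxygen levels and at least 1.5-fold on average, a choice that does not favour a large ambient effect, 41 moved less, and the median interaction signed by the Dox effect was -0.17 (4 of 4 replicate numbers below 0). Without the limit on the fold, a tally added after this result was seen, it was -0.13 over the 61 genes called without the block (48 moved less) and -0.019 over the 356 called with it (203 moved less), each below 0 in 4 of 4 numbers. Median scaling left it at -0.16, which argues against quantile normalization as the source. Whether genes already raised by low oxygen have less room to rise stays open, since the correlation of the signed oxygen effect with the signed interaction was -0.242. The interactions of Efna1 (-0.85), Hey1 (-0.64), Sox9 (-0.60) and Nrarp (-0.56) were not called one by one.

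DAPT may lower the genes that doxycycline raises, by little. With gene sets taken at the other oxygen level, so that no array served both steps, the pair medians averaged -0.075 (SD 0.060) and lay below 0 in 7 of 8 pairs. The exact sign-flip p was 0.0156, or 0.0312 adjusted over 2 tests, where 0.00781 is the smallest that 8 pairs can give. The 8 pairs are the same 4 replicate numbers at both oxygen levels. The test treats them as independent, so its p may be too small. Genes lowered by doxycycline gave 0.057 (exact sign-flip p = 0.242), with 0.14 at ambient oxygen, -0.024 under 1% oxygen and 4 of 8 pairs below 0. Averaged over both oxygen levels, the Nodal target Lefty1 was at -0.53 with DAPT (adjusted p = 0.00972 with the block, lower in 8 of 8 pairs), but not called without it (1.00), and Lefty2 was at -0.56 (0.158 with the block). Both were chosen after their values were seen.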
